A study of Drosophila melanogaster with 2 samples.

How the data were processed

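Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 16 hours after egg laying. The flies carried a transgene for the transcription factor cropped (crp) fused at its C terminus to green fluorescent protein, and the chromatin was precipitated with an antibody against GFP. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the series holds biological replicates 1 and 3 of this single group. The labels name a control experiment, which was not analysed here. With 1 group there is no comparison between conditions, and every test compares sets of regions or genes within the same libraries.

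The deposited data are 8 narrowPeak lists, 4 in the dm6 and 4 in the dm3 build. For each build there is a candidate list per replicate, described in the labels as peaks and background made as input for the irreproducible discovery rate (IDR) procedure, a candidate list from the replicates pooled, and an optimal IDR-thresholded list. The authors gave a signal value for each peak, the peak caller's own measure of enrichment. It was used here to describe, rank or filter peaks, to compare the replicates, and to compare peaks with and without CAGCTG. The authors also deposited −log10 q values, which reach a ceiling of 3.21 in the dm6 IDR list, where 72.9% of the peaks share it, so peaks were not ranked by them. The tenth column, the distance in bp from the start of a peak to its summit, was used to place summits. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Read counts are not part of these lists, so the depth of each library is unknown. Intervals on shares cover counting error only, and peaks and genes along one genome are not independent replicates.

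All coordinates are dm6 unless dm3 is named, and none were converted between builds. The end of every dm6 peak fell within its chromosome arm in the reference assembly. Transcription start sites (TSSs) and gene features came from the Ensembl release 115 annotation, of which the 13968 protein-coding genes on arms 2L, 2R, 3L, 3R, 4, X and Y were used. The analysis was carried out with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

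Replicates were compared by taking from each list as many of the strongest candidates as there are IDR peaks. A candidate counted as shared when at least 50% of the shorter interval overlapped a candidate of the other replicate, and 1000 circular shifts within each arm gave the chance level. Signal values of the replicates were compared at IDR peaks by Pearson's r and Spearman's rho with 100000 permutations. A promoter peak had its summit within 1000 bp of an annotated TSS of a protein-coding gene, and its share was compared by Fisher's exact test with the pooled candidates that overlapped no IDR peak. Hexamers, joined with their reverse complements, were sought in the 101 bp centred on each summit and in windows from 300 to 350 bp on each side of the same summit. A peak had a hexamer within 50 bp when the whole hexamer lay in the 101 bp, whereas single CAGCTG copies counted by their distance from a summit were placed by their midpoints. An exact binomial test compared the peaks with a hexamer only in the centre with those that had it only in the flanks. This was done for the 10 distinct hexamers of the form CANNTG (E-boxes) and for all 2080 hexamers. Genes of 18 lists were tested with Fisher's exact test for an IDR summit within 1000 bp of a TSS, among the genes with a pooled candidate in the same window. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each family at a threshold of 0.05. Intervals of shares are Wilson 95% intervals. For the intervals of odds ratios 0.5 was added to each cell. The odds ratios themselves carry this addition only for arms and for gene lists or groups against the other genes, and are otherwise uncorrected. Counts in other ratios, such as those to arm length, also had 0.5 added.

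Gene lists, tests, most alternatives and the rule for named items were fixed before the data were examined. The rule named the 20 IDR peaks of highest signal with the nearest protein-coding TSS, crp itself, up to 4 members of each list with the strongest promoter peak, all E-box hexamers, the 5 hexamers of lowest p, and the 5 genes with the most IDR summits in the gene body extended by 1000 bp. Of the listed symbols, 4 matched no gene of the annotation and were left out, and older symbols were matched through a table of synonyms. The result of 1 further gene group is not reported here. The alternatives were other windows, overlaps, backgrounds and controls, the 561 IDR peaks with the higher signal, and the strongest candidates of a single replicate in place of the IDR set.

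The procedures were tested on simulated data. For the overlap, 20%, 50% and 80% of the 1122 strongest candidates of replicate 1 were kept unchanged and the rest were shifted. Overlap with the unshifted list was found for 20.3%, 50.2% and 80.1%. The kept peaks overlap themselves, so this checks only the counting of overlaps. Replicates that differ in position, width or rank were not simulated. CAGCTG planted in 5% of peak centres was called in 9 of 10 runs, planted in 10% or 20% in all 10, and unplanted in 0. The other 9 hexamers were called 1 time in the 10 unplanted runs, and 2, 3 and 0 times in the runs with 5%, 10% and 20% planted. A single weak call among these hexamers therefore carries little weight. The simulated flanks were shuffled from the centres themselves, whereas the real flanks differ from the centres in base composition. These counts therefore do not give the rate of false calls in the data. A 3-fold excess of bound genes in the cell cycle list was called in 79 of 100 runs, and an equal share in 0 of 100. These runs drew bound genes from all protein-coding genes, with all 39 members of the list. The test of the data used 22 members among 7075 genes with a candidate, so these rates do not give its power.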

Results

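The data describe where a GFP-tagged copy of cropped was bound in the chromatin of embryos aged 0 to 16 hours. Cropped is the fly relative of the vertebrate factor AP-4, a basic helix-loop-helix leucine zipper protein that binds the E-box CAGCTG. A single group was profiled in 2 biological replicates, numbered 1 and 3. Replicate 1 and replicate 3 each had a list of exactly 30000 candidate peaks, the pooled list held 26505 candidates, and 1122 peaks passed the authors' IDR procedure. The depth of the libraries is unknown, so the replicates' peak lists are the measure of error.

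The IDR peaks had a median width of 404 bp, formed 1029 separate regions and covered 400873 bp. Their signal values ran from 61.3 to 770.4 with a median of 110.1, and no pooled candidate outside the set exceeded 61.1. The IDR set was therefore the 1122 strongest pooled candidates. A candidate was found at 1121 of the IDR peaks in replicate 1, at 1118 in replicate 3, and at 1117 (99.6%) in both. Candidate lists were the input of the IDR procedure, so this presence in both is not independent evidence of agreement. Of the 1122 strongest candidates of replicate 1, 919 (81.9%, 95% interval 79.5 to 84.0%) overlapped one of the 1122 strongest of replicate 3, against a mean of 0.346% over circular shifts (permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction the share was 80.0% (77.6 to 82.3%). The share was 80.4% for the 500 strongest of each replicate, 61.6% for the 2000 strongest, and 27.9% for all 30000, where circular shifts gave a mean of 9.05%.

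Signal values in the replicates' own lists were correlated across the 1117 IDR peaks found in both, with Pearson's r = 0.834 and Spearman's rho = 0.700 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 peaks farthest from the median of replicate 1, r was 0.812. This is a correlation across peaks, which are not independent replicates, and the peaks were selected for high signal in the pooled data. Neighbouring summits at times shared a replicate candidate, so the comparison rests on 1059 candidates of replicate 1 and 1064 of replicate 3. The log2 ratio of replicate 3 to replicate 1 had a median of -0.17 and a standard deviation of 0.57 over peaks.

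**Figure D1:**
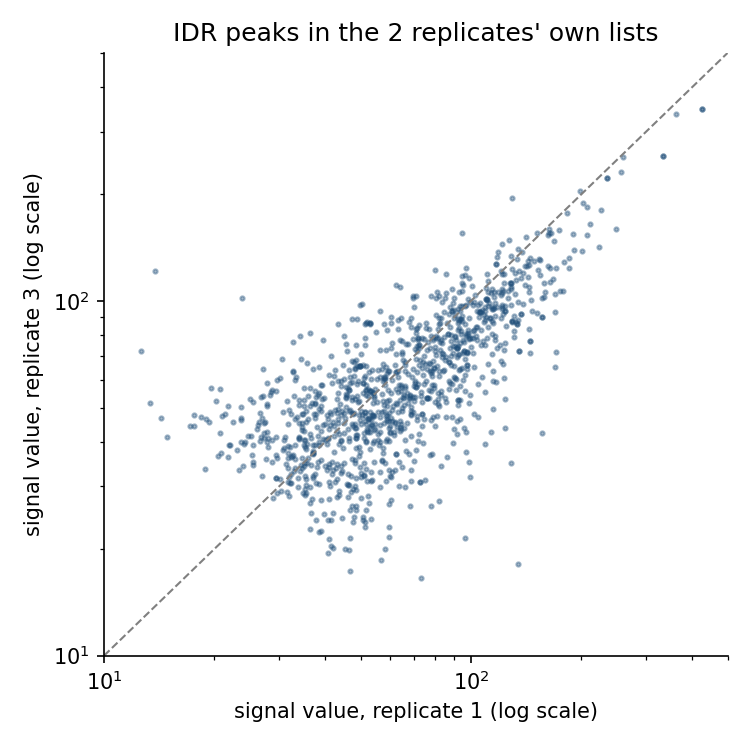
Each point is an IDR peak, placed by the signal value of its overlapping candidate in replicate 1 (x axis) and in replicate 3 (y axis), both on log scales, with the dashed line marking equal values. The 1117 peaks rise together (Pearson's r = 0.834), with wider scatter among the weaker peaks.

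The strongest binding lay at promoters. Summits of 1053 of the 1122 IDR peaks (93.9%, 92.3 to 95.1%) were within 1000 bp of the TSS of a protein-coding gene, against 6704 of 25093 other candidates (26.7%, 26.2 to 27.3%), an odds ratio of 41.9 (95% interval 32.6 to 53.1). Among equally many of the strongest other candidates the share was 50.7%, and in circular shifts it averaged 20.5% (permutation p = 0.001). The summits sat close to the start site: the median absolute distance was 56 bp, 84.0% were within 200 bp, and 75.8% of the promoter summits were upstream of the nearest TSS. By annotation, 605 summits (53.9%) were intergenic, 292 (26.0%) were in a 5′ UTR and 179 (16.0%) in an intron, while 13 (1.16%) were in coding exons. Of the other candidates, 47.8% were intronic and 9.85% were in coding exons.

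The highest peak was at CG9175, at 6098861 to 6099215 on arm 2L. Its summit was intergenic, 64 bp upstream of the TSS, and its signal was 770.4 in the pooled data, 425.8 in replicate 1 and 347.8 in replicate 3. The next was at Tpr2, which encodes a tetratricopeptide co-chaperone, with a signal of 690.8 (361.7 and 336.4 in replicates 1 and 3) and its summit 191 bp upstream of the TSS. HtrA2, a mitochondrial serine protease gene on arm 3R, had 2 of the 20 strongest summits, with signals of 586.0 and 356.7, in a single interval at 14511381 to 14511893. Other genes of mitochondrial function in this group were mTTF, a mitochondrial transcription termination factor (signal 486.1), mIF2, a mitochondrial translation initiation factor (357.6), and milt, an adaptor for the transport of mitochondria (377.0). Genes of vesicle traffic were represented by Slh (408.8) and by RabGGTb, a subunit of Rab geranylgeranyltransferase (386.8). The group also held puml (512.4), timeout, a relative of the clock gene timeless (369.8), the transcription factor gene apt (359.7) and Nmnat, an enzyme of NAD synthesis (328.7). The remaining peaks were nearest to CG10383, CG11050, CG5276, CG34228, CG33228, CG3358 and CG4238, with signals from 328.7 to 449.98. All 20 summits lay within 191 bp of a TSS, 15 of them intergenic, 4 in a 5′ UTR and 1 in an intron, and 15 had CAGCTG within 50 bp.

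The E-box CAGCTG was frequent at the summits, where the other E-boxes were about as rare as in the flanks. CAGCTG was present within 50 bp of the summit in 541 of the 1122 peaks (48.2%, 45.3 to 51.1%) and in the flanks of 71 (6.33%). In 512 peaks it was only in the centre and in 42 only in the flanks (exact binomial adjusted p = 9.01e-103 over 10 hexamers). Of equally many of the strongest other candidates, 13.3% had it in the centre, an odds ratio of 6.08 (4.92 to 7.47). None of the other 9 E-boxes passed the test with the flanks as control. CATATG came closest, in 4.55% of centres and 2.58% of flanks (exact binomial p = 0.0169, adjusted p = 0.0843). CACGTG, the E-box of Myc and Max, was in 1.25% and 1.07%, CACCTG in 4.99% and 4.55%, CAGATG in 5.44% and 4.19%, CAACTG in 7.13% and 5.79%, CAAGTG in 6.86% and 6.33%, CACATG in 3.39% and 2.94%, CAAATG in 8.65% and 9.18%, and CAATTG in 3.57% and 4.46%. CATATG did pass with the 561 peaks of higher signal (adjusted p = 0.0228) and with flanks starting at 500 bp (adjusted p = 0.0127), in exact binomial tests.

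In the scan of all 2080 hexamers CAGCTG had the lowest p, and 163 hexamers were more frequent in the centres and 222 in the flanks at an adjusted p under 0.05. The next were ACAGCT (42.2% of centres), AACAGC (37.5%), AGCTGA (34.9%) and ATCAGC (25.7%), which overlap CAGCTG in sequence: between 90.0% and 96.4% of the peaks with one of them in the centre had CAGCTG there too. The centres held 39.9% G and C and the flanks 44.6%, a difference that enters the scan. Of the 1319 CAGCTG copies within 250 bp of an IDR summit, 641 (48.6%, 45.9 to 51.3%) had their midpoint within 50 bp, against an even share of 20% (exact binomial p = 4.4e-119). CAGCTG was more frequent at stronger peaks, in 35.2% (29.9 to 41.0%) of the centres in the 281 weakest peaks, 46.1% and 53.9% in the 280 peaks of each of the next ranks of signal, and 57.7% (51.8 to 63.3%) in the 281 strongest. The median signal was 121.2 for peaks with the site and 100.9 for peaks without it (permutation p = 0.0001, the smallest that 10000 permutations can give).

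**Figure D2:**
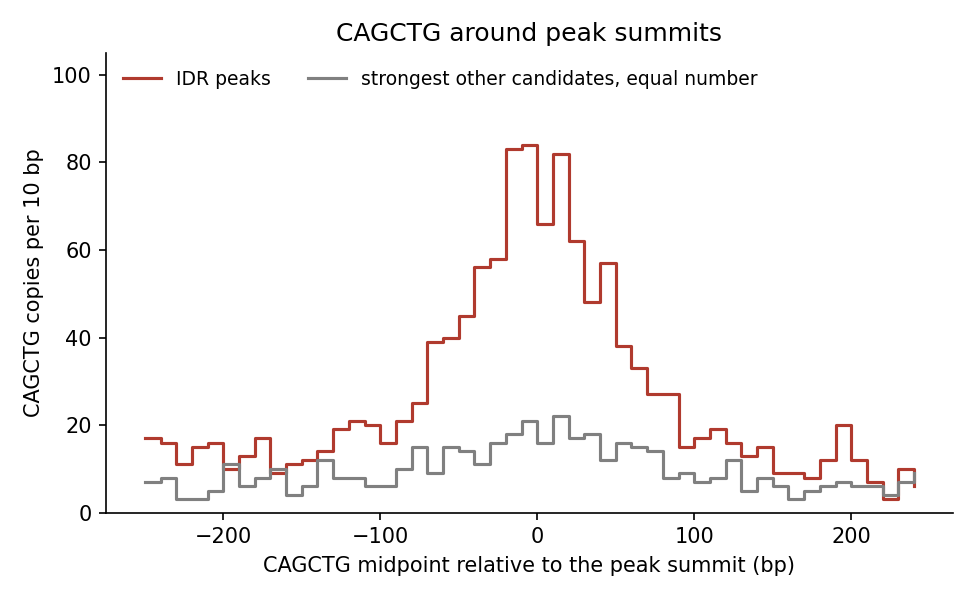
Copies of CAGCTG per 10 bp (y axis) by the distance of their midpoint from the summit in bp (x axis), for the 1122 IDR peaks (red) and for equally many of the strongest other candidates (grey). Copies gather at the IDR summits, with 641 of 1319 within 50 bp.

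Which kinds of genes carried a promoter peak was tested for 18 lists. An IDR summit was within 1000 bp of a TSS of 1550 genes, which is 21.9% of the 7075 genes with any pooled candidate in that window. Members of the ribosome biogenesis and cell cycle lists had the highest shares, and chemoreceptor genes had none. For ribosome biogenesis, 8 of 20 members had a peak (40.0%, odds ratio 2.43, 95% interval 1.02 to 5.82, Fisher's exact adjusted p = 0.414). The strongest were Polr1B, a subunit of RNA polymerase I (signal 194.1), Nnp-1 (134.8), Bka (132.6) and Rrp40, of the RNA exosome (117.0). For the cell cycle, 8 of 22 members had one (36.4%, odds ratio 2.09, 0.897 to 4.89, Fisher's exact adjusted p = 0.414). These included the mitotic kinase aurA (signal 249.0, 156.5 in replicate 1 and 90.4 in replicate 3), the replication licensing factor dup (237.3), fzy, an activator of the anaphase-promoting complex (210.2), and the mitosis-triggering phosphatase stg (154.9), whose summit lay 20 bp upstream of a TSS. Neither list passed the threshold.

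The odorant and gustatory receptors had a peak at 0 of 28 members with a candidate, the single list past the threshold (odds ratio 0.0622, 0.0038 to 1.02, Fisher's exact adjusted p = 0.0348). A count of 0 left the interval reaching 1.02. The call of this exact test ended with a 500 bp window (adjusted p = 0.169), with the 5′-most TSS (0.0565), with the 561 stronger peaks (0.48) and without replicate 1 (0.16), and over all alternatives the adjusted p ran from 2.16e-05 to 0.48. The pan-neuronal list also had 0 of 11 members with a peak and the segmentation and Hox list 0 of 13, neither past the threshold (Fisher's exact adjusted p = 0.414 for each).

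Among bHLH factors 5 of 24 had a peak (Fisher's exact adjusted p = 1), the strongest at tai (signal 166.8), crp itself (129.9), SREBP, a regulator of lipid synthesis (112.8), and Mondo, a sugar-responsive factor (78.8). Cytosolic ribosomal protein genes had 13 of 67 (Fisher's exact adjusted p = 0.92), led by RpL24-like (396.6), RpL34b (198.6), RpS28a (155.8) and RpL37-1 (122.0). This list was taken mainly by the symbol prefixes RpL and RpS, so RpL24-like is in it by its name alone. The RpL24-like peak is the one assigned above to CG5276, 255 bp upstream of the RpL24-like TSS and nearer to that of CG5276. In the insulin and TOR list 3 of 17 members had a peak (17.6%, against 21.9% of all genes with a candidate), namely Tsc1 (142.1), Sesn (118.6) and gig (73.5). These are known restraints on TOR signalling, but whether such genes carry peaks more often was not tested. In the muscle list 3 of 21 did, namely the transcription factor Mef2 (215.7), Tm1 (170.8) and Msp300 (94.4), and in the germline list 3 of 9, namely orb (204.7), nanos (173.8) and Hsp26 (66.3).

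Every other list had 2 members with a peak. They were crq (211.9) and ush (127.5) of 10 hemocyte genes, fry (186.9) and Appl (120.2) of 24 genes of dendrite morphogenesis and axon guidance, neur (145.8) and Psn (125.2) of 16 Notch genes, and bs (131.3) and mmy (84.8) of 22 tracheal genes. They were also cnk (121.2) and RasGAP1 (68.9) of 17 EGFR and Ras genes, Fer2LCH and Fer1HCH, which share 1 peak (81.4), of 7 gut and fat body genes, Eip75B (78.9) and Ldh (72.1) of 20 ecdysone genes, and Hsp26 (66.3) and Hsp27 (63.4) of 13 heat shock genes. None of the lists from the bHLH factors to the heat shock genes passed the threshold. Most have few members, so only large differences could pass. The share of the 67 cytosolic ribosomal protein genes, 19.4%, was close to the 21.9% of all genes with a candidate (odds ratio 0.882, 0.484 to 1.60). With all protein-coding genes as background the odds ratio of this list was above 1 (1.35, 0.754 to 2.40) and did not pass either.

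**Figure D3:**
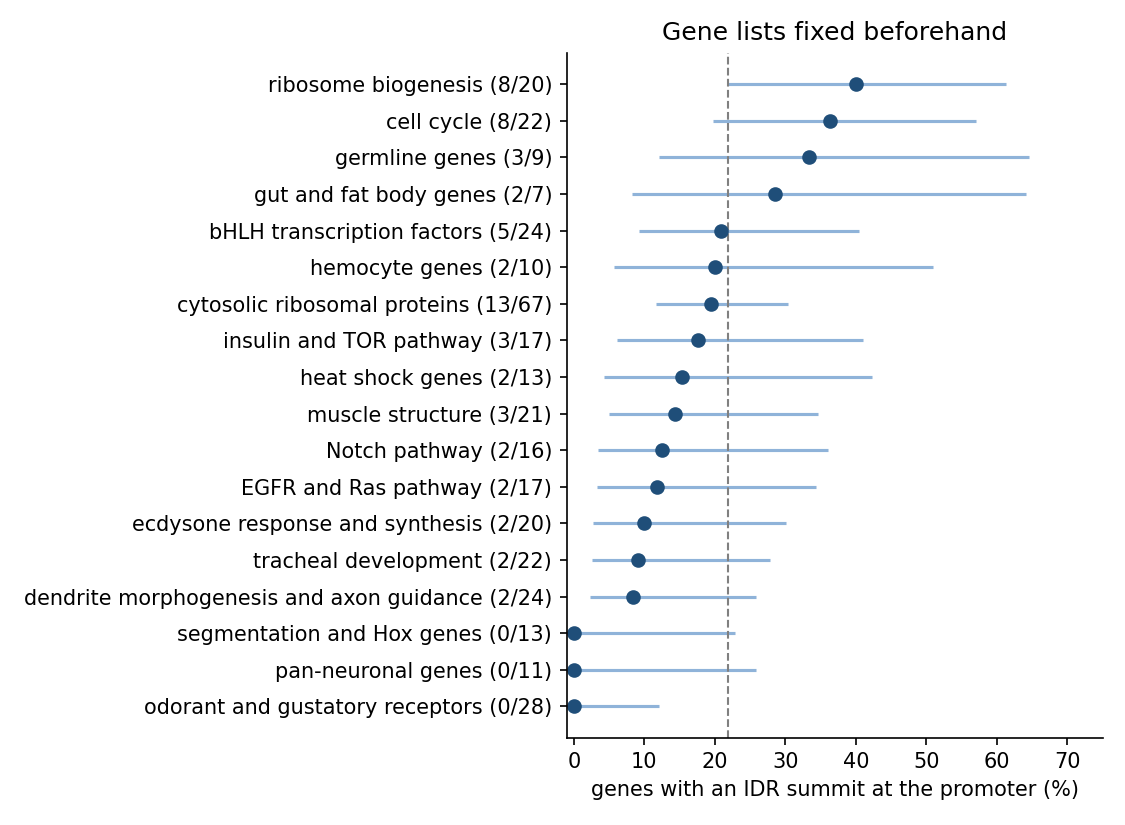
Share of the genes of each list that had an IDR summit within 1000 bp of a TSS (points, with Wilson 95% intervals), among members with any candidate there. The dashed line is the share over all such genes, 21.9%, and the counts stand beside the list names.

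At crp, the tagged gene itself, peaks were dense. The gene lies on the minus strand of arm 2L at 16263556 to 16287730. The locus extended by 20000 bp on each side (64175 bp) held 9 IDR peaks and 60 pooled candidates, against medians of 0 and 12 in windows of this size over the main arms. More IDR peaks were present than in 99.96% of the windows, and more pooled candidates than in 99.99%. Replicate 1 had 52 candidates there and replicate 3 had 69, each against a median of 14. Of the 9 IDR summits 8 were inside the gene, 6 of these in introns and 2 in the 5′ UTR, and the ninth was in the 5′ UTR of CG17328. The strongest, with its summit at 16286199 in an intron, had a signal of 135.9 (51.5 in replicate 1 and 86.1 in replicate 3), and a summit at 16287405 in the 5′ UTR, 325 bp downstream of a TSS, had 129.9. CAGCTG was in the centre of 4 of the 9. Of the 69 IDR summits more than 1000 bp from any TSS in the genome, 6 were among these 9. The flies carry a crp transgene, so reads here can come from it as well as from the native gene.

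With its 8 summits, crp had more IDR summits in the gene body extended by 1000 bp than any other gene. It was followed by ush, a cofactor of GATA factors, with 5, and by Dhc64C, a dynein heavy chain gene, the overlapping genes Mi-2 and Su(Tpl), and neur, a ubiquitin ligase of the Notch pathway, with 4 each.

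**Figure D4:**
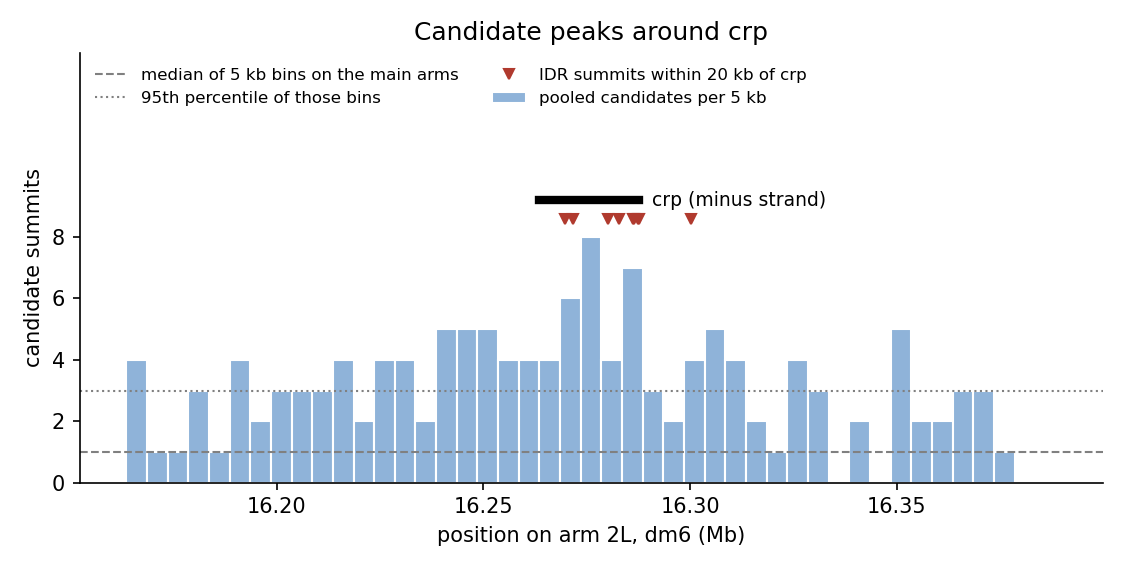
Pooled candidate summits per 5000 bp (bars, y axis) along arm 2L around crp (x axis, Mb, dm6), with the IDR summits within 20000 bp of the gene as triangles and the gene as a black bar. Bins over crp hold up to 8 candidates, against a median of 1 (dashed line) and a 95th percentile of 3 (dotted line) over all bins of the main arms.

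By arm, IDR peaks were more frequent on 2R and less frequent on 3L and 4 than the other candidates. Arm 2R held 21.1% of the IDR peaks and 16.9% of the others (odds ratio 1.32, Fisher's exact adjusted p = 0.00126), and arm 3L 19.3% and 22.4% (odds ratio 0.831, Fisher's exact adjusted p = 0.0361). Arm 4, the small and largely heterochromatic chromosome, held 2 IDR peaks and 633 other candidates (odds ratio 0.0861, Fisher's exact adjusted p = 3.48e-09). The shares of 2L, 3R and X did not pass the threshold, and arm Y had no peak in either set. The call for 3L ended in 4 alternatives, with adjusted p up to 0.374 against arm length. Arm X, with an odds ratio of 0.853, passed as depleted in 3 alternatives, with the 561 stronger peaks (odds ratio 0.536, Fisher's exact adjusted p = 0.000108), without replicate 1 (odds ratio 0.725, Fisher's exact adjusted p = 0.00218) and against arm length (ratio 0.657, exact binomial adjusted p = 1.45e-07). Against arm length 2L (ratio 1.30, exact binomial adjusted p = 2.88e-05) and 3R (ratio 1.11, adjusted p = 0.0473) also passed as enriched, and Y, with 0 peaks, as depleted (adjusted p = 9.33e-13). The ratio of arm 4 to its length was 0.217. Arm Y had no pooled candidate at all, so no peak there could have passed. Arm length also takes no account of the number of copies of X and Y in embryos of mixed sex.

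The dm3 and dm6 lists of the same libraries gave IDR sets close in number, 1095 and 1122 peaks, with median signals of 111.9 and 110.1 and highest signals of 768.2 and 770.4. Whether they hold the same regions was not tested. The candidate lists differed more. The pooled list held 13674 peaks in dm3 and 26505 in dm6, and that of replicate 1 held 18915 and 30000, while replicate 3 had 30000 in both. Genes of structural RNAs were rarely under the IDR peaks: 0 of 1122 overlapped a tRNA, snRNA or rRNA gene, which allows a share of up to 0.267%, and 1 overlapped a snoRNA gene. Of the other candidates 36 (0.143%) overlapped a tRNA gene and 41 (0.163%) a snoRNA gene.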

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

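The alternatives that keep the strongest summit of each merged region, leave out the crp locus or set the null share by window positions were chosen after the data were seen, and the others before. The replicate overlap, the correlation of signal values, the promoter share, the excess of CAGCTG in peak centres and its closeness to summits kept their direction and passed their tests in every alternative run, CAGCTG being tested among the 10 E-boxes. The promoter share ran from 88.6% to 98.2%. Its odds ratio, 41.9 in the main setting, was 23.7 without replicate 1 and 57.8 without replicate 3. It was 14.8 against equally many of the strongest other candidates and 151 with the 561 IDR peaks of higher signal. In the 69 peaks far from a TSS CAGCTG passed among the 10 E-boxes (exact binomial adjusted p = 0.026). Other counts changed. The 561 IDR peaks of higher signal are fewer by construction. The number of E-boxes called rose from 1 to 2 with those peaks, with 1 summit per merged region and with flanks from 500 bp. CATATG was the addition each time. With dinucleotide shuffles as control the number rose to 4. CACCTG (1.56 times its shuffled count), CAGATG (1.40) and CATATG (1.76) were added under that control. CACATG, not called in the main test, changed direction and passed at 0.632 times its shuffled count. These calls and that of CAGCTG all had the same permutation p = 0.0198 (adjusted p = 0.0396), the smallest that 100 shuffles can give in a two-sided test. The hexamers more frequent in centres numbered 93 with the 561 peaks and 0 with the 69 far peaks, where fewer peaks were tested. There CAGCTG ranked 4 in the scan of all hexamers and did not pass it, against rank 1 in the other settings of the scan. With arm length as background 6 arms differed in place of 3. The 1 gene list past the threshold, the chemoreceptors, became 0 with the 561 peaks, with a 500 bp window and with the 5′-most TSS, and ran from 0 to 1 when either replicate was left out. The cause was not tested for the E-box, arm and gene list counts. Of the other tests of single items in the alternatives, 88 of hexamers, 27 of arms and 136 of gene lists kept their direction and side of the threshold. A further 22 of hexamers and 22 of gene lists changed direction without passing the threshold under either setting, and 6 of hexamers and 5 of arms newly passed it, while 4 of arms and 4 of gene lists no longer did, all in the same direction. The depth of the libraries is unknown, so its effect on the number of weak peaks could not be assessed.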

Other observations

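Gene groups outside the fixed lists were looked at after the strongest peaks had been seen, as were the promoter orientation, the site flanks and the occupancy of single sites, the number of candidates away from promoters at crp, the candidates there without CAGCTG or with it, the search for other E-boxes and the wider search for TATCGA. Several groups, mitochondrial and other, carried promoter peaks often, and 7 of the 8 groups tested are given here. Among genes with a candidate, 37 of 61 mitochondrial ribosomal protein genes had an IDR summit at the promoter (60.7%, odds ratio 5.56, 95% interval 3.33 to 9.29, Fisher's exact adjusted p = 4.86e-10 over 8 groups), led by mRpL11, whose peak is the one shared with HtrA2 (signal 586.0), mRpL32 (249.7), mRpL51 (213.0) and mRpS9 (195.8). The subunits of respiratory complex I had 15 of 25 (Fisher's exact adjusted p = 0.00011), among them ND-B18 (238.0) and ND-19 (210.0). Peaks were as frequent at aminoacyl-tRNA synthetase genes, 15 of 25 (Fisher's exact adjusted p = 0.00011), a group that is not mitochondrial as a whole: LeuRS-m (239.4) and AlaRS-m (207.9) bear the mitochondrial suffix, and TrpRS (196.6) and TyrRS (191.4) do not. Proteasome subunits had 2 of 26, TAF genes 1 of 12, odorant-binding proteins 0 of 13 and cuticular proteins 1 of 19, none past the threshold. The share of mitochondrial ribosomal proteins exceeded that of proteasome subunits (odds ratio 18.5, 3.71 to 60.7, Fisher's exact p = 3.47e-06) and that of cytosolic ribosomal proteins (odds ratio 6.40, 2.82 to 13.5, Fisher's exact p = 1.95e-06). These pairs were not among the fixed tests and their p-values are unadjusted, so they only describe the difference between the groups.

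Promoter summits of the IDR set often had TSSs of both strands nearby. Of 1053 such summits, 598 (56.8%) had TSSs of both strands within 1000 bp. Among promoter summits of other candidates 1220 of 6704 did (18.2%, odds ratio 5.91, 5.15 to 6.77, Fisher's exact p = 1.4e-142). The sets were not matched for distance to the TSS, and whether cropped acts on both genes was not tested. The bases beside the core also differed between copies at summits and copies elsewhere. At CAGCTG copies within 50 bp of an IDR summit, 37.1% of the sides read AACAGCTG and 22.3% ATCAGCTG, against 6.94% and 5.45% at copies elsewhere, whereas TGCAGCTG made 0.78% and 11.3%. Few copies of the core lay at an IDR summit: 641 of the 62338 on the arms (1.03%, 0.952 to 1.11%) had one within 50 bp of their midpoint. Copies farther from a summit or at weaker candidates are not counted, so this is not the share of bound copies. The share was 13.4% (12.4 to 14.4%) for the 4245 copies within 200 bp of a TSS and 0.127% (0.101 to 0.16%) for the rest.

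The first pattern weighed is the set of 581 IDR peaks (51.8%) without CAGCTG within 50 bp of the summit. Promoters with TATCGA, part of a core promoter element, might have been called without the site, but TATCGA was less frequent in these peaks than in peaks with CAGCTG (13.6% and 25.5%, odds ratio 0.46, 0.34 to 0.625), and also when both hexamers were sought within 200 bp (23.3% and 40.6%, odds ratio 0.444, 0.316 to 0.633), which argues against this as the whole cause, although it stays open for a part, as TATCGA was in 3.27% of the flanks of these peaks. Displaced summits may account for many: CAGCTG lay 51 to 200 bp from the summit in 59.6% of these peaks and over 300 and up to 450 bp away in 16.9%, and the peaks with it only in the nearer windows outnumbered those with it only in the farther ones 7.79 times (exact binomial p = 5.7e-49), while in other promoter candidates without a central copy the shares were 13.7% and 13.5%. Another E-box may stand in for a small part, as 1 of the other 9, CATATG, was in 7.06% of these centres and 2.41% of their flanks (adjusted p = 0.00242, exact binomial test). Counting also copies that straddle the edges at 50 bp, CAGCTG was absent within 200 bp in 206 peaks (18.4% of the IDR set), and the single group offers no biological contrast.

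The second pattern is the share of IDR peaks at promoters, which any open promoter might give in a ChIP experiment. Promoter summits of the IDR set held CAGCTG in 49.5% of centres and those of other candidates in 6.86%. The odds ratio was 13.3 (11.4 to 15.5, Fisher's exact p = 4.87e-236), so the site set the IDR promoter summits apart from the others. Those candidates were not matched to the IDR peaks for signal, distance to the TSS or accessibility. The comparison therefore cannot exclude accessibility as the cause. Accessibility as a condition for binding remains open, and a control experiment was not analysed here. No biological explanation was tested.

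For the third pattern, the density of candidates at crp, a locus rich in CAGCTG is a possible explanation in part, as its 52 copies exceeded those of 98.6% of windows. With 10000 bp on each side its 46 copies, against a median of 20, exceeded those of 99.82%, and with 50000 bp its 69 copies, against a median of 58, exceeded those of 75.8%, while its pooled candidates within 50000 bp still exceeded those of 99.97%. As the whole cause it is opposed by the candidates without CAGCTG within 200 bp of the summit, which numbered 40 against a median of 10 and exceeded those of 99.93% of windows, although the 60 candidates at crp held CAGCTG within 50 bp more often than candidates elsewhere (15% and 6.42%, odds ratio 2.57, 1.34 to 5.38, Fisher's exact p = 0.014). Candidates more than 1000 bp from a TSS, 42 against a median of 8, exceeded those of 99.99% of windows, but they are part of the pattern itself and do not decide between extra copies of the locus on the transgene and binding of cropped within its own gene. Both stay open for the candidates within the gene, as the extent of the transgene was not known here. Bins of 5000 bp beside the gene also held more candidates than the median bin, which had 1. Those from 16243556 to 16263555 held 4 or 5 each, and those from 16288556 to 16308555 held 2 to 5. Binding within the gene would not give these, which argues against it as the whole cause. Extra copies stay open for them.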
